A study of Homo sapiens with 12 samples.

How the data were processed

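RNA from ChagoK1 cells, an established human lung cancer line, was sequenced as stranded mRNA libraries. The cells carried a doxycycline-inducible short hairpin against MAGOHB, and induced cells received doxycycline at 100 ng/mL for 5 days, per the labels' protocols. The 12 libraries fell into 4 groups of 3: parental cells, in which MAGOH is hemizygously deleted, with and without doxycycline, and cells with V5-tagged MAGOH re-expressed, with and without doxycycline. Groups and replicates were taken from the sample labels. Nothing in the labels said that replicates came from separate cultures, so p-values per transcript rested on the spread between these libraries, which may be technical. Tests over sets of transcripts or genes measured the spread across those transcripts or genes, not between libraries.

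Reads were demultiplexed with bcl2fastq 2.18 and processed with kallisto and sleuth against GRCh38, per the submitters' processing notes, where the versions of kallisto and sleuth were not given. The annotation release was not given in the sources used here. The authors deposited 1 table per context of sleuth Wald test results, per the file headers. Each listed 178136 transcripts with a coefficient, its standard error, a p-value, a q-value, the mean observed abundance, variance terms, the gene and the transcript biotype. The coefficients, standard errors and mean abundances deposited by the authors were read as natural log values, since no header named the base. That base was inferred from the values: the lowest mean abundance of a tested transcript was 0.503 in the parental table and 0.514 in the MAGOH-V5 table, near what a filter of 5 reads and an offset of 0.5 give on the natural log scale. The p-value and q-value columns deposited by the authors matched a two-sided normal p of coefficient over standard error, and its Benjamini-Hochberg adjustment, within 1e-06 in all 76250 tested rows of the parental table and all 74135 of the MAGOH-V5 table. The deposited variance terms matched a model of 3 against 3 libraries with no batch term, within a relative 1e-06, in the same rows. The variance used by the authors was the larger of the observed and the fitted value, so transcripts with little spread were not called from a chance low variance.

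No header said which way the coefficient ran. It was read as induced minus uninduced because every tested MAGOHB transcript, the target of the hairpin, had a negative coefficient in both tables. Coefficients and standard errors were divided by the natural log of 2 and are given as log2 changes ± SE. The abundance of a group was recovered as mean abundance plus or minus 0.5 of the coefficient and is given as a geometric mean of normalised estimated counts. The sleuth offset of 0.5 counts sets the fitted change of a transcript that is near 0 in a group, so where all libraries of a group were at 0 the fold is given as a lower bound against a floor of 3 counts in the group's geometric mean.

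Library depths were unknown, since the tables held no values per library. Summed geometric mean counts of the tested transcripts came to 34.1 in the parental table and 33.9 in the MAGOH-V5 table, in units of 1e+06 counts, and these are approximations to the depth of an average library after normalisation. The median SE was 0.26 log2 in the parental table and 0.28 log2 in the MAGOH-V5 table for transcripts at or above the median abundance, and 1.32 and 1.33 log2 for those below it. The tables were normalised separately, so levels were tested only within a table.

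Transcripts with a q-value under 0.05 in the authors' table were counted by direction. Called transcripts annotated as nonsense-mediated decay (NMD) or retained intron were compared with called protein-coding transcripts by Fisher's exact test, two-sided. Within each gene, the inverse-variance mean change of its NMD or retained-intron transcripts was set against that of its coding transcripts. The sum of these shifts over genes was tested with 100000 sign flips, two-sided. Sizes are given as medians over genes, and a permutation p given with a median is that of the sum. Genes are not independent replicates in these tests. Intervals of medians came from 1000 bootstrap resamples of genes. Differences between contexts were tested per transcript as the difference of the coefficients over its combined SE with a normal p, adjusted by Benjamini-Hochberg over 69145 transcripts tested in both tables. Lists of genes fixed before the data were examined were tested with limma's cameraPR on the Wald statistic of 1 transcript per gene, the one of highest mean abundance, with a preset inter-gene correlation of 0.01 and adjustment over lists. That transcript was chosen in each context separately, whatever its biotype, so the transcript standing for a gene can differ between contexts. For differences between contexts it was chosen by the mean over both. An inter-gene correlation could not be estimated without values per library, so presets of 0.05 and 0.1 were run in its place. Lists with fewer than 3 tested genes were not tested. Of the list of 15 snoRNA host genes, 0 had a tested transcript. The transcripts listed by the authors included only 5 annotated as lincRNA or antisense, so this does not show that the host genes were unexpressed.

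The transcripts named were fixed by a rule before the data were examined. It took every tested transcript of MAGOHB and MAGOH, the most abundant transcript of each core exon junction complex gene, the 12 largest changes per context and direction and the 10 largest differences between contexts per direction. These came from transcripts past the threshold and at or above the median abundance, with 1 transcript per gene, the one with the smallest q-value, and no clone-style symbols; larger changes of other isoforms are left out by this choice. It also took 2 to 4 members of each reported list with the smallest q-values, and the NMD and retained-intron transcripts with the smallest q-values. Any other transcript is said to have been chosen after its values were seen. Coordinates are those of GENCODE 29 on GRCh38, matched by versioned transcript ID for 159513 of the 178136 transcripts (89.5%).

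Alternatives fixed before the data were examined were other q-value thresholds, Bonferroni adjustment, a minimum fold of 1.5, an abundance filter, other summaries per gene, other preset correlations, ranks, and a t distribution with 8 degrees of freedom. A moderated variance (limma squeezeVar), subtraction of the median coefficient, the tests of the isoform shifts between contexts, a retained-intron reference for the NMD shift, the shifts of processed transcripts, the matched comparisons, the junction test and the comparison by exon number were added after the data were seen. On simulated data for the difference between contexts, with 69145 transcripts, 26 of 100 seeded differences of 1 log2 and 10 of 100 of 0.5 log2 were called. There was 1 call among 68945 unchanged transcripts. With so few seeded differences the adjustment was stricter than in the data, where 7784 transcripts passed. These shares therefore do not give the sensitivity of the test in the data. A seeded NMD shift of 0.5 log2 was recovered as 0.51 in 4163 genes of the parental table and 3968 genes of the MAGOH-V5 table. In permuted parental statistics of 15988 genes, cameraPR called 19 of 20 lists shifted by 5 in the Wald statistic and 1 of 20 unshifted lists. Permuted statistics hold no inter-gene correlation, so this did not test the preset. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and R 4.3.3 with limma 3.58.1, were used.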

Results

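The series measured transcript abundance in ChagoK1 lung cancer cells in which MAGOHB was depleted by an inducible hairpin. MAGOHB and its near-identical paralog MAGOH encode a core subunit of the exon junction complex, the protein complex that splicing leaves on mRNA near exon junctions and that takes part in nonsense-mediated decay. Per the series design, the question was how MAGOHB loss acts on the transcriptome of cells with a hemizygous MAGOH deletion, against the same cells with MAGOH restored. Each of the 4 groups had 3 libraries. The authors' deposited tables tested 76250 transcripts of 16946 genes in parental cells and 74135 transcripts of 16910 genes in MAGOH-V5 cells, and values per library were not analysed here.

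The direction of change was read from MAGOHB, the target of the hairpin, so its fall is an assumption here and only its size was measured. In parental cells its most abundant transcript, ENST00000539554.5 (GRCh38 chromosome 12, 10606013 to 10613591, minus strand), fell by 2.38 ± 0.16 log2 (SE, q = 2.4e-50 in the authors' deposited table), from a geometric mean of 604 to 115 normalised counts. The coding transcript ENST00000320756.6 fell by 2.11 ± 0.26 log2 in parental cells and by 2.91 ± 0.32 log2 in MAGOH-V5 cells (q = 8.7e-15 and 4.4e-17 in the authors' deposited tables). Of the other MAGOHB transcripts, ENST00000544176.1, ENST00000544850.5 and ENST00000545236.5 fell in parental cells, with changes of -2.19, -1.94 and -1.25 log2, and ENST00000537852.5 changed by -1.23 log2 without passing the test (q = 0.078 in the authors' deposited table). In MAGOH-V5 cells ENST00000539554.5, ENST00000544850.5 and ENST00000545236.5 fell, with changes of -5.41, -2.56 and -2.24 log2, ENST00000544176.1 fell by 6.42 ± 1.44 log2, and ENST00000537852.5 changed by -0.99 log2 (q = 0.42 in the authors' deposited table). Summed over 6 tested transcripts, MAGOHB retained 23.7% of its uninduced level in parental cells and 8.85% in MAGOH-V5 cells. The sums were not tested. Between contexts the changes of ENST00000539554.5 and ENST00000544176.1, which fell to 10.5 counts and under 3 counts in MAGOH-V5 cells, differed by 3.03 ± 1.05 and 4.24 ± 1.45 log2 (adjusted p = 0.038 and 0.035). The difference of 0.80 ± 0.41 log2 for ENST00000320756.6 did not pass (adjusted p = 0.26), nor did those of the other 3 transcripts.

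The main MAGOH transcript, ENST00000371470.7 (GRCh38 chromosome 1, 53226892 to 53238610, minus strand, 5 exons), moved in opposite directions. It fell by 0.31 ± 0.11 log2 in parental cells (q = 0.030 in the authors' deposited table) and rose by 0.74 ± 0.10 log2 in MAGOH-V5 cells (q = 4.7e-11 in the authors' deposited table). The difference of -1.05 ± 0.15 log2 passed the test between contexts (adjusted p = 4.5e-10). Reads of the re-expressed MAGOH were not separated from those of the endogenous gene. In MAGOH-V5 cells the counts may thus be mostly those of the re-expressed MAGOH, and the difference does not show opposite regulation of the MAGOH gene. The other MAGOH transcripts did not pass the test in either table: ENST00000371466.4 changed by 0.38 and -0.04 log2, ENST00000495868.1 by 1.32 and 0.94 log2, and ENST00000462941.1, tested in MAGOH-V5 cells, by -0.36 log2. Summed over its tested transcripts, uninduced MAGOH stood at 735 normalised counts in the parental table and 33937 in the MAGOH-V5 table. The ratio was 46.2, between separately normalised tables. Uninduced MAGOHB stood at 1503 and 1260 counts in those tables. The assignment of reads among isoforms was not examined here. The parental MAGOH call did not pass with a moderated variance (adjusted p = 0.099).

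**Figure D1:**
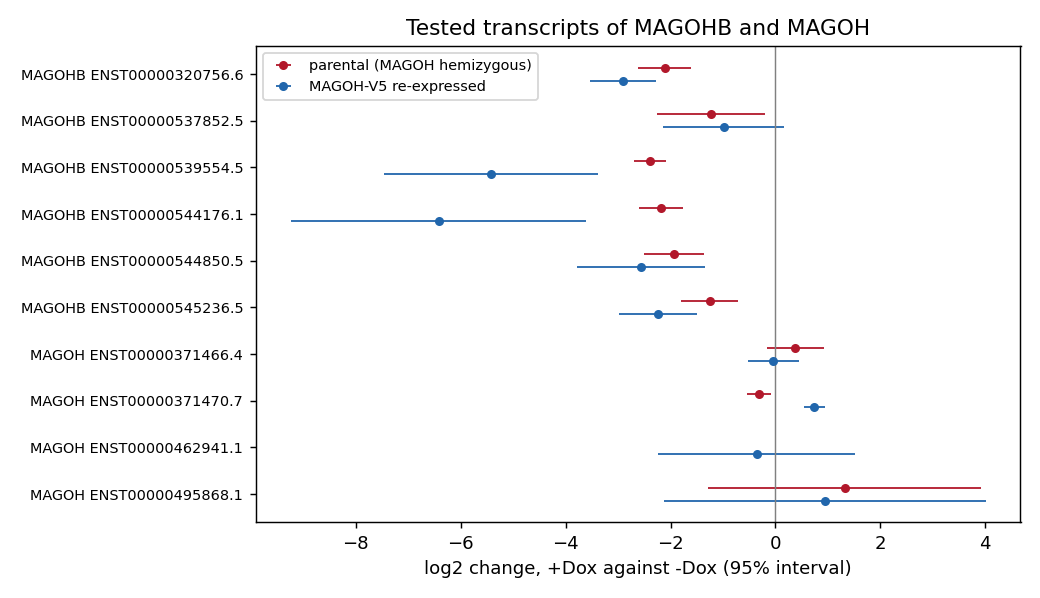
Log2 change with doxycycline (x axis, 95% interval) of each tested MAGOHB and MAGOH transcript (y axis) in parental cells (red) and MAGOH-V5 cells (blue). The direction was set so that MAGOHB lies below 0, and the main MAGOH transcript, ENST00000371470.7, lies at -0.31 in parental and 0.74 in MAGOH-V5 cells.

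In parental cells the stress-responsive secreted factor GDF15 rose by 4.51 ± 0.11 log2, from 149 to 3409 counts. The transcription factors DDIT3 and ATF3 rose by 3.13 ± 0.15 and 2.93 ± 0.11 log2, and the keratin KRT6A by 5.21 ± 0.25 log2. The calcium-binding protein S100A4 fell by 3.74 ± 0.26 log2 and the ferric reductase CYBRD1 by 3.52 ± 0.16 log2. In all, 16726 transcripts of 9473 genes passed q under 0.05 in the authors' deposited table, 8405 higher and 8321 lower. The balance depended on scaling and abundance. With the median coefficient subtracted first 7390 were higher and 9560 lower, and among abundant transcripts 7168 and 8437. With each gene taken by its transcript of smallest q, large rises were also those of the growth factor FGF19 (5.84 ± 0.46 log2), KLHDC7B (5.40 ± 0.36 log2), the phosphatase PTPRH (5.13 ± 1.06 log2) and single isoforms of ATP5B (5.71 ± 0.36 log2), LETMD1, U2AF1, UBXN1, GRB10, PPP1R12B, ARMC10 and SDHB. Other isoforms, left out by that choice, moved as far or further, such as HNRNPH1 ENST00000503105.5 at 6.14 log2. The 7 from LETMD1 to SDHB started from 3.32 to 22.5 counts and had an SE between 0.93 and 2.02 log2. By the same choice large falls were those of GPR146, SEMA5A, the immediate early gene FOS, STAC2, FAM178B and SYNPO, with changes of -3.26, -3.24, -3.16, -3.05, -3.02 and -2.94 log2. OSBPL9 ENST00000475697.5, a retained-intron isoform, fell by 2.96 log2, and isoforms of PLEC, ZSWIM8 and HIST2H4B fell with an SE over 1.2 log2. PPP1R12B, ARMC10 and HIST2H4B did not pass with a moderated variance (adjusted p = 0.066, 0.057 and 0.065), and Bonferroni adjustment left 6183 calls.

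NMD-annotated isoforms rose in parental cells. EIF4A2 ENST00000425053.5, an isoform of a translation initiation helicase (chromosome 3, 186783577 to 186789881), rose by 2.02 ± 0.07 log2 from 3342 to 13553 counts. SRSF3 ENST00000477442.6 (chromosome 6, 36594391 to 36602040) rose by 2.76 ± 0.10 log2, and HNRNPDL ENST00000349655.8 (chromosome 4, 82424629 to 82429447) by 3.21 ± 0.12 log2; both genes encode RNA-binding splicing regulators. The annotated NMD isoforms of the ribosomal protein genes RPL13A and RPL3 rose, the first from 699 to 5597 counts and the second by 2.34 log2, and that of the snRNP core gene SNRPB by 2.23 log2. Of 1398 called NMD transcripts 1113 were higher (79.6%), against 5237 of 11508 coding transcripts (45.5%), an odds ratio of 4.68 (95% interval 4.08 to 5.35, Fisher's exact test, p = 2.8e-135). Within 4163 genes the NMD isoforms shifted by a median of 0.63 log2 against the coding isoforms (95% interval 0.59 to 0.67), and 75.4% of genes had a positive shift (permutation p = 1e-05, the smallest that 100000 sign flips can give). Among falling NMD isoforms were those of SNRNP70, MEGF6 and SPATA20, at -1.70, -1.82 and -1.64 log2.

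Other isoforms without an intact reading frame moved as well in parental cells. Retained-intron isoforms shifted by a median of 0.10 log2 against coding isoforms in 5893 genes (95% interval 0.08 to 0.12, permutation p = 1e-05, the smallest possible), and processed transcripts by 0.33 log2 in 5178 genes (95% interval 0.29 to 0.36). Across genes the retained-intron values ran the other way. Their median change was -0.07 log2. Against coding transcripts matched on abundance, length and GC content it was -0.20 (95% interval -0.22 to -0.18), -0.15 and -0.07 log2. The retained-intron isoforms RPS12 ENST00000484616.2, EIF4A2 ENST00000494445.1 and FTH1 ENST00000533138.1 rose by 2.33, 1.81 and 3.08 log2. Of 2125 called retained-intron transcripts 954 were higher, an odds ratio of 0.98 against coding transcripts (95% interval 0.89 to 1.07, Fisher's exact test, p = 0.62).

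**Figure D2:**
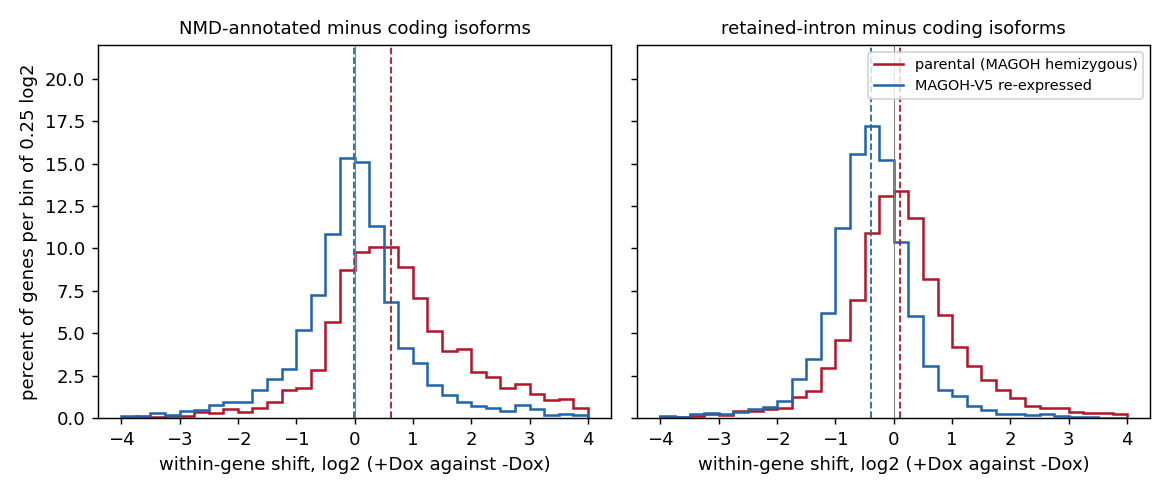
Distribution over genes of the within-gene shift of NMD-annotated (left) and retained-intron (right) isoforms against coding isoforms; the x axis is the shift in log2, the y axis the percent of genes per bin, and dashed lines are medians. Parental cells (red) have medians of 0.63 and 0.10, MAGOH-V5 cells (blue) of -0.01 and -0.39; up to 3.44% of genes lie beyond 4 log2 and are not drawn.

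Stress programmes rose in parental cells. Of 21 genes of the ATF4 programme, the amino acid and integrated stress response, 18 rose, 0 fell and 3 did not pass (20 rose when adjusted over the list alone), with a median change of 1.46 log2 (cameraPR adjusted p = 4.4e-27). TRIB3, SESN2 and PHGDH rose by 1.83 ± 0.07, 2.67 ± 0.10 and 1.41 ± 0.07 log2. Of 15 genes of the endoplasmic reticulum unfolded protein response 12 rose and 1 fell, also when adjusted over the list alone (median 0.48 log2, cameraPR adjusted p = 6.3e-08), with DNAJB9 at 1.71 ± 0.08 and SEL1L at 0.93 ± 0.06 log2. Of 24 mRNAs reported as NMD-sensitive 17 rose and 3 fell, also when adjusted over the list alone (median 0.79 log2, cameraPR adjusted p = 3.5e-10). Among them DDIT3, ATF3 and IFRD1 rose, and the HNRNPDL coding isoform ENST00000602300.5 fell by 1.54 ± 0.08 log2. That list shares 13 tested genes with other lists here. Of the 11 that no other list holds, 10 rose and 1 fell in parental cells, and 8 rose and 0 fell in MAGOH-V5 cells (medians 1.23 and 0.68 log2). These 11 include ATF4 itself, at 0.80 and 0.68 log2, which was chosen after its values were seen. They therefore do not separate NMD sensitivity from the ATF4 programme.

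Genes of the decay and junction complexes also moved in parental cells. Of 12 NMD factors 8 rose and 1 fell, also when adjusted over the list alone (median 0.32 log2, cameraPR adjusted p = 0.044, and 0.11 and 0.21 with preset correlations of 0.05 and 0.1). UPF3B, UPF1 and SMG8 rose by 1.29 ± 0.17, 0.43 ± 0.07 and 0.60 ± 0.10 log2. Of 12 factors associated with the exon junction complex 6 rose and 2 fell, and 7 rose when adjusted over the list alone (cameraPR adjusted p = 0.018, and 0.057 and 0.14 at the higher presets), with PNN at 0.83 ± 0.06 and RNPS1 at 0.58 ± 0.08 log2. Of 5 core genes 4 fell, also when adjusted over the list alone, MAGOHB itself among them (cameraPR adjusted p = 0.018, but 0.066 at a preset of 0.1, 0.071 with the mean of all coding transcripts and 0.0501 with ranks). The fall of MAGOHB is the assumption that set the direction. The list was not tested without it, so the set test does not show that the other core genes fell as a set. RBM8A, the partner of MAGOH (chromosome 1, 145921556 to 145927536), fell by 0.71 ± 0.07 log2 and CASC3 (chromosome 17, 40140323 to 40172183) by 0.28 ± 0.06 log2, and EIF4A3 (chromosome 17, 80135214 to 80147183) changed by 0.00 ± 0.06 log2 (q = 0.99 in the authors' deposited table).

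Of other groups in parental cells, 4 fell and G2/M genes rose. All 13 mitochondrially encoded mRNAs fell, also when adjusted over the list alone (median -0.70 log2, cameraPR adjusted p = 4.0e-04), with MT-ATP6 at -1.08 ± 0.10 log2. Of 17 cholesterol synthesis genes 13 fell and 1 rose, also when adjusted over the list alone (median -0.48 log2, cameraPR adjusted p = 4.0e-04), with the lanosterol synthase LSS at -1.50 ± 0.09 and the sterol-binding protein STARD4 at -1.19 ± 0.10 log2. Of 13 epithelial markers 11 fell and 1 rose, and 2 rose when adjusted over the list alone (median -0.43 log2, cameraPR adjusted p = 0.0021, and 0.052 at a preset of 0.1). KRT19 and CLDN4 changed by -0.99 ± 0.06 and -0.75 ± 0.06 log2, and the transcription factor OVOL1 rose by 1.05 ± 0.09 log2. Of 26 hnRNP genes 13 fell and 1 rose, and 16 fell and 2 rose when adjusted over the list alone (cameraPR adjusted p = 0.020, and 0.11 and 0.25 at the higher presets), with HNRNPH1 at 1.58 ± 0.08 and HNRNPH2 at -0.98 ± 0.07 log2. Of 27 genes of G2/M and mitosis 12 rose and 2 fell, also when adjusted over the list alone (median 0.16 log2, cameraPR adjusted p = 0.0049, and 0.054 and 0.15 at the higher presets), with CDC20 at 1.01 ± 0.06 and PLK1 at 0.72 ± 0.07 log2.

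In MAGOH-V5 cells GDF15 rose by 3.21 ± 0.15 log2, from 171 to 1592 counts. The keratin KRT17 rose by 3.11 ± 0.18 log2, the glutathione-degrading enzyme CHAC1 by 2.61 ± 0.20 log2 and the lysyl oxidase LOXL2 by 2.65 ± 0.25 log2. The growth factor binding protein IGFBP3 fell by 2.04 ± 0.18 log2 from 22373 to 5436 counts, and CYFIP2 fell by 2.19 ± 0.14 log2. In all, 6240 transcripts of 4690 genes passed q under 0.05 in the authors' deposited table, 3770 higher and 2470 lower. Other large rises were those of the serine protease KLK7, ANXA3, the alkaline phosphatase ALPPL2, C12orf75, C2orf54, KNDC1 and the chaperone CLGN, between 2.63 and 3.29 log2, and an NMD isoform of PAIP1 rose by 4.92 ± 1.27 log2. Other large falls were those of the amino acid transporter SLC6A19 and of CHST2, CETN2 and TMEM25, at -2.71, -2.47, -2.04 and -2.01 log2, and of retained-intron isoforms of NR4A1 and CSNK1D, at -2.11 and -2.07 log2. Isoforms of RNF145, LIMA1 and ATAD3A fell with an SE over 1.5 log2 and did not pass with a moderated variance (adjusted p = 0.077, 0.053 and 0.11), which gave 3489 calls, 3051 of them among the 6240, while Bonferroni adjustment left 1554.

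Isoform shifts in MAGOH-V5 cells were as follows. Of 299 called NMD transcripts 197 were higher, an odds ratio of 0.92 against coding transcripts (95% interval 0.72 to 1.18, Fisher's exact test, p = 0.52). The within-gene NMD shift had a median of -0.01 log2 in 3968 genes (95% interval -0.03 to 0.02, permutation p = 0.89). NMD isoforms of MTHFD2, FTH1, OPN3, CKB, RPL13A and UQCRH rose by 1.67, 1.09, 1.49, 1.42, 1.06 and 0.93 log2, and those of PCBP2, RPF2 and SRSF6 fell, with changes of -1.52, -1.69 and -0.70 log2. Retained-intron isoforms fell. Of 705 called transcripts 579 were lower, an odds ratio of being higher of 0.10 against coding transcripts (95% interval 0.08 to 0.13, Fisher's exact test, p = 2.9e-142). Their within-gene shift had a median of -0.39 log2 in 5801 genes (95% interval -0.41 to -0.37, permutation p = 1e-05, the smallest possible), and processed transcripts shifted by -0.12 log2 in 4943 genes. Retained-intron isoforms of WSB1, RPL13 and UBE3C rose by 1.07, 0.80 and 2.09 log2.

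Of the 21 ATF4 programme genes 19 rose and 0 fell in MAGOH-V5 cells, also when adjusted over the list alone (median 1.42 log2, cameraPR adjusted p = 4.4e-40), with PHGDH at 1.68 ± 0.09 and TRIB3 at 1.42 ± 0.09 log2. Of 78 cytosolic ribosomal protein genes 72 rose and 0 fell, and 75 rose when adjusted over the list alone (median 0.51 log2, cameraPR adjusted p = 6.7e-27), with RPL12 at 0.84 ± 0.10 and RPL10 at 0.65 ± 0.09 log2. Of 15 unfolded protein response genes 9 rose and 1 fell, and 13 rose when adjusted over the list alone (cameraPR adjusted p = 5.8e-04), with XBP1 at 0.75 ± 0.09 and EDEM1 at 0.67 ± 0.10 log2. Of 24 reported NMD-sensitive mRNAs 11 rose and 5 fell, and 12 rose when adjusted over the list alone (cameraPR adjusted p = 0.0015, and 0.12 at a preset of 0.1); ATF3 and ASNS rose by 1.70 ± 0.13 and 1.75 ± 0.15 log2. Of 27 G2/M genes 13 rose and 0 fell, and 15 rose and 1 fell when adjusted over the list alone (cameraPR adjusted p = 0.0065, and 0.061 and 0.18 at the higher presets), with AURKA at 0.99 ± 0.15 and CDC20 at 0.57 ± 0.09 log2. Of 23 p53 targets 7 rose and 2 fell, and 8 rose and 4 fell when adjusted over the list alone (cameraPR adjusted p = 0.011, and 0.068 and 0.18 at the higher presets). The rises included GDF15 and SESN2, which other stress pathways also induce, BTG2 fell by 0.88 ± 0.10 log2, and CDKN1A changed by -0.02 ± 0.16 log2 (q = 0.98 in the authors' deposited table); CDKN1A was chosen after its values were seen.

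Falls in MAGOH-V5 cells included 8 of 29 G1/S and DNA replication genes, with 3 rising (12 fell and 4 rose when adjusted over the list alone; cameraPR adjusted p = 0.0012, and 0.12 at a preset of 0.1). E2F2 and RRM2 changed by -1.21 ± 0.13 and -0.77 ± 0.09 log2. Of 13 SR proteins 6 fell and 0 rose, and 1 rose when adjusted over the list alone (cameraPR adjusted p = 0.0035, and 0.10 at a preset of 0.1), with SRSF8 at -0.69 ± 0.10 and SRSF6 at -0.37 ± 0.09 log2. Of 26 hnRNP genes 8 fell and 3 rose, and 11 fell when adjusted over the list alone (cameraPR adjusted p = 0.0035, and 0.14 at a preset of 0.1), with HNRNPF at -0.48 ± 0.09 and HNRNPM at -0.45 ± 0.09 log2. Of 12 NMD factors 3 fell and 0 rose, and 1 rose when adjusted over the list alone (cameraPR adjusted p = 0.048, and 0.11 and 0.20 at the higher presets), with DHX34 at -0.52 ± 0.10 and UPF2 at -0.49 ± 0.10 log2. Of 8 tested mitochondrially encoded mRNAs 4 fell, and 5 fell and 1 rose when adjusted over the list alone (cameraPR adjusted p = 0.026, and 0.061 and 0.14 at the higher presets), with MT-ATP8 at -0.69 ± 0.14 and MT-ND6 at -0.48 ± 0.11 log2. RBM8A fell by 0.43 ± 0.09 log2, and EIF4A3 and CASC3 changed by 0.17 ± 0.09 and 0.02 ± 0.09 log2 (q = 0.29 and 0.97 in the authors' deposited table).

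**Figure D3:**
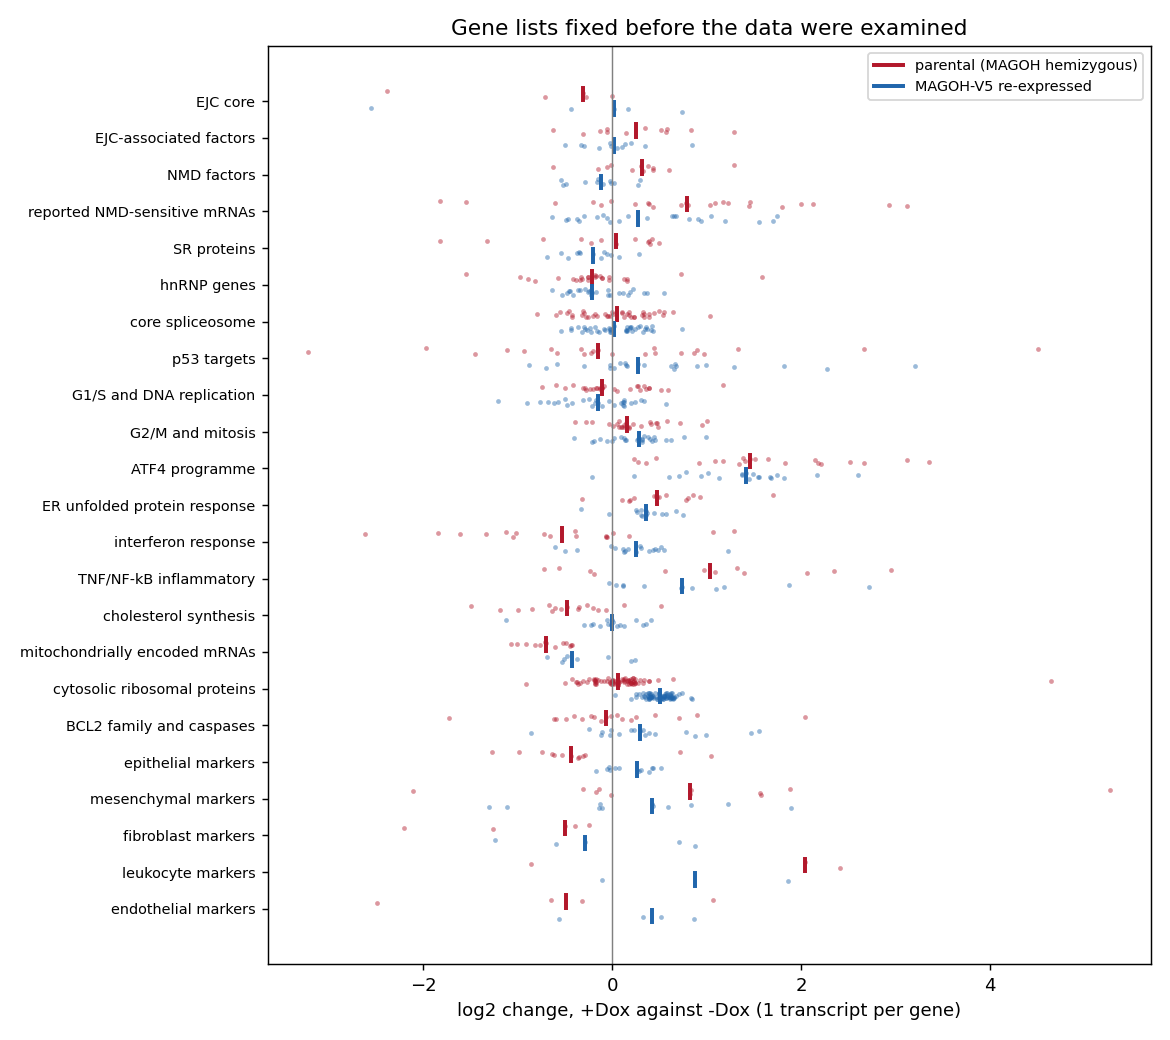
Log2 change with doxycycline (x axis) of each measured gene, 1 transcript per gene, in the gene lists (y axis), with bars at list medians; red is parental cells and blue MAGOH-V5 cells. ATF4 programme medians are 1.46 and 1.42, and those of cytosolic ribosomal proteins 0.06 and 0.51.

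The contexts were compared directly by testing the difference of their changes. PNN, a factor associated with the exon junction complex, rose in parental cells and fell by 0.30 log2 in MAGOH-V5 cells, a difference of 1.13 ± 0.10 log2 (adjusted p = 2.3e-24). UPF3B rose in parental cells and changed by -0.01 log2 in MAGOH-V5 cells, a difference of 1.30 ± 0.26 log2 (adjusted p = 1.4e-05). DDIT3 rose more in parental cells, by 1.57 ± 0.20 log2 (adjusted p = 2.6e-12). CLDN4 and KRT19 differed by -1.13 ± 0.11 and -1.27 ± 0.15 log2, STARD4 by -1.55 ± 0.14 log2 and the ribosomal protein gene RPL22 by -0.95 ± 0.12 log2 (adjusted p = 8.9e-24, 3.6e-14, 2.2e-26 and 2.2e-12). Of 69145 transcripts tested in both contexts, 7784 differed at an adjusted p under 0.05, with 2869 more positive and 4915 more negative in parental cells, and a t distribution with 8 degrees of freedom left 2929. With median coefficients subtracted 2225 were more positive and 6025 more negative, and a moderated variance gave 10094 calls. Among coding isoforms lost in parental cells, HNRNPDL ENST00000295470.9, RBMX ENST00000562646.5, PRRC2B ENST00000320547.7 and ARID2 ENST00000444670.5 went from 685, 519, 666 and 342 counts to 0. They were at least 228-fold, 173-fold, 222-fold and 114-fold lower, and with their MAGOH-V5 changes of -0.28, -1.69, 0.12 and -0.69 log2 they passed the difference test (adjusted p = 4.3e-46, 4.9e-17, 2.5e-09 and 6.4e-04). Isoforms of RNMT, SRPK1, EPS15L1, WDR11 and SF1 fell in parental cells to under 1 count from 599, 346, 289, 262 and 826 counts and also differed, as did SPTAN1, which passed in neither table alone.

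HNRNPH1 ENST00000503105.5 rose by 6.14 log2 in parental cells, from 59.4 to 4221 counts, and changed by 0.61 log2 in MAGOH-V5 cells (difference 5.53 ± 0.46 log2, adjusted p = 1.3e-30). Isoforms of UBE2J2, RPS6KB1, MRPL3 and MARS rose in parental cells by 3.24, 2.96, 4.47 and 3.60 log2, against -0.93, -1.30, 0.64 and -0.23 log2. BAG1 ENST00000634734.1 fell from 1400 to 237 counts in parental cells and from 898 to 0.0396 counts in MAGOH-V5 cells, and isoforms of AGO2, which passed in neither table alone, MIB2, BAG6 and MAGOHB also differed, with 1.58 to 4.24 counts left in induced MAGOH-V5 cells.

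By list, NMD factors, factors associated with the exon junction complex and reported NMD-sensitive mRNAs had more positive changes with doxycycline in parental than in MAGOH-V5 cells, with median differences of 0.44, 0.33 and 0.44 log2 (cameraPR adjusted p = 7.8e-04, 0.0023 and 7.8e-04, and 0.049, 0.070 and 0.084 at a preset of 0.1). Adjusted over each list alone, 6 of 12, 6 of 12 and 12 of 24 members had a more positive change and 1, 1 and 4 a more negative one, and over all transcripts 5, 6 and 9 had a more positive one. These lists overlap and are not separate results. NMD factors share UPF3A and UPF3B with the associated factors, and SMG1, SMG5 and UPF2 with the NMD-sensitive mRNAs. Epithelial markers, cytosolic ribosomal proteins and cholesterol synthesis genes had more negative changes, with median differences of -0.63, -0.44 and -0.35 log2 and 10 of 13, 62 of 78 and 10 of 17 members more negative when adjusted over the list alone (cameraPR adjusted p = 4.2e-04, 4.1e-08 and 0.0038, and 0.049, 0.049 and 0.11 at a preset of 0.1). G1/S genes differed by a median of 0.23 log2 (adjusted p = 0.0020, and 0.13 at a preset of 0.1) and unfolded protein response genes by 0.13 log2 (adjusted p = 0.026, and 0.092 and 0.20 at the higher presets), with differences of 1.44 ± 0.15 and 1.11 ± 0.11 log2 for DNAJB9 and DNAJC3 and of -0.89 ± 0.11 log2 for CALR. The ATF4 programme differed by a median of 0.09 log2 (adjusted p = 0.074).

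The within-gene NMD shift was larger in parental than in MAGOH-V5 cells by a median of 0.59 log2 over 3807 genes (95% interval 0.54 to 0.64), and the retained-intron shift by 0.47 log2 over 5553 genes (95% interval 0.44 to 0.49; permutation p = 1e-05 for both, the smallest possible). Processed transcripts, which are not annotated as NMD targets, differed by 0.44 log2 over 4640 genes (95% interval 0.41 to 0.46). Among abundant transcripts the differences were 0.42, 0.40 and 0.28 log2 for NMD, retained-intron and processed transcripts. The size of the NMD difference depended on the reference. Against retained-intron isoforms of the same gene, a comparison added after the data were seen, the NMD shift was 0.56 log2 in parental and 0.37 log2 in MAGOH-V5 cells, a difference of 0.17 log2 over 2409 genes (95% interval 0.11 to 0.22).

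Changes in the contexts correlated across 69145 transcripts with Pearson's r = 0.21 and Spearman's rho = 0.22; transcripts are not independent replicates, and no library was shared between the tables. Among transcripts past the threshold, 1314 were higher in both contexts, against 415 for independent lists, and 1518 lower in both, against 294. GDF15, TRIB3 and CHAC1 were among those higher, and S100A4, CYBRD1 and IGFBP3 among those lower. Opposite directions were found for 689 transcripts that fell in parental and rose in MAGOH-V5 cells, against 447 for independent lists, and for 127 that rose in parental and fell in MAGOH-V5 cells, against 273.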

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

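The tests of isoform shifts between contexts, the retained-intron reference for the NMD shift and both tests of the ATF4 programme were chosen after the results were seen; the matched comparisons and the junction test were written down before their own values were seen. All results here were set apart because the change with doxycycline differed between contexts by a test of the difference. In total 7784 transcripts differed, among them the main MAGOH transcript ENST00000371470.7, by -1.05 log2 (parental minus MAGOH-V5, as throughout). For that transcript the counts in MAGOH-V5 cells include those of the re-expressed MAGOH, so the endogenous gene was not compared alone. Median differences were 0.33 log2 for factors associated with the exon junction complex, 0.44 log2 for NMD factors and 0.44 log2 for reported NMD-sensitive mRNAs. They were 0.23 log2 for G1/S and DNA replication genes and 0.13 log2 for unfolded protein response genes. Cholesterol synthesis genes differed by -0.35 log2, cytosolic ribosomal proteins by -0.44 log2 and epithelial markers by -0.63 log2. At a preset correlation of 0.1 only the differences of NMD factors, ribosomal proteins and epithelial markers passed, and that of the unfolded protein response was lost at 0.05 (adjusted p = 0.092). The NMD isoform shift differed by 0.59 log2 and the retained-intron shift by 0.47 log2.

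NMD-annotated isoforms such as those of EIF4A2, SRSF3 and HNRNPDL rose against coding isoforms in parental cells. Across genes, low abundance and transcript length, each taken alone, do not account for the whole rise. NMD isoforms stood 0.52 log2 above coding transcripts of matched abundance and 0.57 log2 above those of matched length, each with its 95% interval above 0.2. The within-gene shift was not matched on either, so these values do not decide the question for it. Over genes with both kinds, NMD isoforms rose 0.56 log2 more than retained-intron isoforms in parental cells. The same measure was 0.37 log2 in MAGOH-V5 cells, where the NMD shift had a median of -0.01 log2. A positive value thus arose there without a rise of NMD isoforms. The test therefore cannot decide whether more intron-containing RNA in the induced libraries added to the rise. A hypothesis that stays open is a loss of junction-dependent decay. It predicts a rise of coding transcripts with a junction more than 55 bases past the stop codon. In 238 genes these shifted by a median of 0.42 log2 against other coding transcripts of the same gene in parental cells. In MAGOH-V5 cells the shift was 0.13 log2 (95% interval -0.04 to 0.27). The difference was 0.32 log2 over 206 genes (95% interval 0.08 to 0.44), as the hypothesis predicts. Processed transcripts, which are not annotated as NMD targets, also shifted upward in parental cells, by 0.33 log2. The junction test therefore cannot separate a loss of decay from a shift of isoforms in general. Much of the NMD difference between contexts may instead lie in a general shift of non-coding isoforms. With the retained-intron reference the NMD difference fell to 0.17 log2, and processed transcripts differed by 0.44 log2. Among abundant transcripts the differences were 0.42, 0.40 and 0.28 log2 for NMD, retained-intron and processed transcripts. Differences in library quality could not be examined without values per library.

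Retained-intron isoforms, including those of NR4A1 and CSNK1D, fell against coding isoforms in MAGOH-V5 cells. Across genes, abundance, length and GC content, each taken alone, do not account for the fall. Retained-intron isoforms stood at -0.39, -0.43 and -0.42 log2 against coding transcripts matched on each in turn, with 95% intervals below -0.15. The within-gene shift was not matched on them, so these values do not decide the question for it. A difference in the share of unspliced RNA between libraries remains open and was not tested, and no biological explanation was tested.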

How the results depend on the processing

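Moderated variances, median-centred coefficients, the shift differences between contexts and the higher preset and ranks for differences between lists were added after the data were seen. No paired analysis was possible because the tables held no values per library; for the same reason the planned runs without each replicate and with a replicate block, and counts over other splits of the libraries, were not run. Directions of the parental NMD shift and of both retained-intron shifts, and their side of the threshold, were the same under the other within-gene summaries, but sizes were not. Among abundant transcripts the parental retained-intron shift was 0.06 log2, against 0.10, and processed transcripts shifted by 0.19 and -0.07 log2 in parental and MAGOH-V5 cells, against 0.33 and -0.12. Against matched coding transcripts the parental retained-intron value was -0.20 log2 by abundance, opposite to the within-gene shift of 0.10; the cause was not tested. Calls in parental cells numbered 6183 under Bonferroni adjustment, and calls in MAGOH-V5 cells 4108 at q under 0.01, 1554 under Bonferroni adjustment and 3489 with a moderated variance, of which 3051 were among the 6240; the first 3 follow from a stricter threshold, and the cause of the last was not tested. Differing transcripts numbered 2929 with a t distribution. The MAGOH-V5 NMD shift turned to 0.0147 log2 among abundant transcripts (permutation p = 0.91), a median near 0 on either side. The odds ratio for NMD transcripts in MAGOH-V5 cells was 0.93 over all tested transcripts by sign (Fisher's exact test, p = 0.0058), and for retained-intron transcripts in parental cells 0.90 among abundant and 0.85 over all tested transcripts (Fisher's exact test, p = 0.041 and 3.1e-17), against 0.98 among called ones; the cause was not tested. The correlation between contexts was 0.38 among transcripts called in either table and 0.28 among abundant ones; the cause was not tested. Lists called numbered 7 and 5 in parental cells with preset correlations of 0.05 and 0.1, against 11. In MAGOH-V5 cells they numbered 7, 3 and 7 with the presets and with ranks, against 11, and 3 of 8 differences between lists held at 0.1, those of NMD factors, ribosomal proteins and epithelial markers; with the mean of all coding transcripts the calls for the exon junction complex core (adjusted p = 0.071), its associated factors (0.068) and NMD factors (0.066) ended in parental cells, and that for NMD factors (0.059) in MAGOH-V5 cells. Ranks ended those for the core (0.0501) and associated factors (0.072) in parental cells, for NMD factors (0.056), mitochondrially encoded mRNAs (0.056), p53 targets (0.13) and NMD-sensitive mRNAs (0.23) in MAGOH-V5 cells, and for the difference in the unfolded protein response (0.095), while the interferon difference passed (0.033). A higher preset widens the test's error by construction; the cause of the other losses was not tested. At a preset of 0.1 the calls for the ATF4 programme and the unfolded protein response held in both contexts, as did those for NMD-sensitive mRNAs, cholesterol synthesis and mitochondrially encoded mRNAs in parental cells and ribosomal proteins in MAGOH-V5 cells. Below the median abundance the median SE was 1.32 and 1.33 log2, so for many of those transcripts a 2-fold change would not pass.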

Other observations

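Both tests of the ATF4 programme below were chosen after its rise was seen. Some gene groups have not been described so far. Of 18 tested interferon response genes in parental cells 3 rose and 6 fell, also when adjusted over the list alone, with OAS3 at -1.05 ± 0.09 and OAS1 at -1.61 ± 0.14 log2; in MAGOH-V5 cells 4 of 19 rose and 1 fell, and 5 rose when adjusted over the list alone (cameraPR adjusted p = 0.33 and 0.49). The difference had a median of -0.78 log2 (cameraPR adjusted p = 0.055), and 7 of 18 members, OAS3 and IFIT1 among them, had a more negative change with doxycycline in parental cells. Of 12 tested inflammatory NF-kB genes 5 rose and 3 fell in parental and 3 rose in MAGOH-V5 cells, also when adjusted over the list alone, with NFKB2 at 1.09 ± 0.12 and 1.18 ± 0.12 log2 and IL6 at 2.96 ± 0.41 and 1.87 ± 0.56 log2 (cameraPR adjusted p = 0.33 and 0.12). In the BCL2 family and caspases PMAIP1, a BH3-only gene, rose by 2.04 ± 0.20 and 1.56 ± 0.18 log2, among 3 rises and 5 falls of 19 in parental and 5 rises and 1 fall in MAGOH-V5 cells, and 4 rises in parental cells when adjusted over the list alone (cameraPR adjusted p = 0.72 and 0.20). SNAI1 rose by 1.89 ± 0.22 and 0.84 ± 0.15 log2, among 4 and 2 rises of 11 mesenchymal markers, also when adjusted over the list alone (cameraPR adjusted p = 0.25 and 0.51).

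The other lists did not pass as sets. Of 42 core spliceosome genes 15 rose and 13 fell in parental cells, with SNRPD3 at -0.79 ± 0.06 and BUD31 at 1.03 ± 0.10 log2, and 8 rose and 5 fell in MAGOH-V5 cells; adjusted over the list alone these were 15 and 13, and 11 and 9 (cameraPR adjusted p = 0.47 and 0.77). Of 13 SR proteins in parental cells 5 rose and 5 fell, also when adjusted over the list alone, with SRSF2 at -1.82 ± 0.18 and TRA2B at 0.49 ± 0.07 log2 (cameraPR adjusted p = 0.96). Among the rises was SRSF6, for which the NMD isoform ENST00000483871.6 was taken in parental cells, here and among the reported NMD-sensitive mRNAs. Its coding transcript ENST00000244020.4, taken in MAGOH-V5 cells, changed by -0.39 log2 in parental and -0.37 log2 in MAGOH-V5 cells. Of 23 p53 targets in parental cells 8 rose and 7 fell, and 10 rose when adjusted over the list alone, with GDF15 rising and BTG2 at -1.97 ± 0.09 log2 (cameraPR adjusted p = 0.076). Of 29 G1/S genes in parental cells 10 rose and 9 fell, and 11 rose and 11 fell when adjusted over the list alone, with CDT1 at 1.18 ± 0.06 and CCNE1 at -0.75 ± 0.10 log2 (cameraPR adjusted p = 0.47). Ribosomal protein genes in parental cells had 12 rises and 11 falls of 78, and 14 rises when adjusted over the list alone (cameraPR adjusted p = 0.25); the RPS9 transcript ENST00000620540.4, a processed transcript, rose by 4.65 ± 0.15 log2. Cholesterol synthesis genes in MAGOH-V5 cells had 2 rises and 1 fall of 17, and 3 rises when adjusted over the list alone, with INSIG1 at -1.13 ± 0.12 log2 (cameraPR adjusted p = 0.38), and epithelial markers 4 rises of 13, also when adjusted over the list alone, with CLDN7 at 0.43 ± 0.09 log2 (cameraPR adjusted p = 0.20). Factors associated with the exon junction complex had 0 rises and 2 falls of 12 in MAGOH-V5 cells, and 1 rise when adjusted over the list alone (cameraPR adjusted p = 0.38), and the core genes 1 rise and 2 falls of 5, also when adjusted over the list alone (cameraPR adjusted p = 0.78). Markers of other cell types were few: fibroblast markers had 0 and 1 rises of 5, endothelial markers 1 fall of 4 in parental cells, that of KDR at -2.49 ± 0.24 log2, and leukocyte markers 1 fall of 3 in parental cells, that of CSF1R at -0.87 ± 0.20 log2. Adjusted over the list alone these counts were the same, except 1 rise of endothelial markers in parental cells and 1 rise and 1 fall in MAGOH-V5 cells (cameraPR adjusted p in parental cells = 0.72, 0.47 and 0.98 for fibroblast, endothelial and leukocyte markers, and 0.77 and 0.85 in MAGOH-V5 cells for the first 2).

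The ATF4 programme, with TRIB3, PHGDH and SESN2, rose in both contexts. If MAGOH re-expression restores junction-dependent decay, a loss of decay of these mRNAs as the whole cause would be removed with it, yet the list's median in MAGOH-V5 cells was 97.0% of that in parental cells. The list's genes differed between contexts by a median of 0.0935 log2 (95% interval -0.04 to 0.52), with 13 of 21 more positive in parental cells. Mean changes of the list lay further apart than the medians, at 1.59 log2 in parental and 1.29 log2 in MAGOH-V5 cells. MAGOHB retained 23.7% of its uninduced level in parental and 8.85% in MAGOH-V5 cells. The rises were therefore not compared at equal depletion. An effect of doxycycline or of hairpin induction itself cannot be told apart from MAGOHB loss acting apart from MAGOH, since no group received doxycycline without the hairpin against MAGOHB.

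By exon number, the most abundant coding transcripts of genes with 21 or more exons changed by a median of -0.19 log2 in parental cells (95% interval -0.23 to -0.15) and those with 1 exon by -0.06 log2 (95% interval -0.15 to 0.01). For 2 to 5, 6 to 10 and 11 to 20 exons the parental medians were -0.08, -0.04 and -0.09 log2. In MAGOH-V5 cells the medians for 1, 2 to 5, 6 to 10, 11 to 20 and 21 or more exons were -0.05, 0.14, 0.15, 0.07 and 0.01 log2. Spearman's rho with exon number was -0.0480 and -0.0503 in parental and MAGOH-V5 cells, and with transcript length -0.0297 and -0.222.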
